A study of Mus musculus with 6 samples.

How the data were processed

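Total RNA of 6 mouse kidney samples, 3 labelled Cre-negative and 3 labelled Cre-positive, was biotin-labelled with the manufacturer's whole-transcript protocol and hybridised to 1 Affymetrix array each, per the labels' protocols. The authors deposited 1 table of log2 values after RMA, a method that by its definition corrects background, quantile-normalizes arrays and summarises probes per probe set. RMA and Partek are named in the submitters' processing notes, without versions, and the genome build and annotation behind the probe sets are not given in the sources used here, so no coordinates are printed. That the deposited values are log2 was read from RMA's convention and from their range, 1.89 to 13.6 in all arrays. RMA compresses differences of dim probe sets, so fold changes near the lower end of the scale are understated. Scanner files, slides and scan dates were not used here, so background correction could not be varied and no batch could be tested. There were 0 columns of other samples.

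The table held 41345 rows. GEO's platform annotation gave 23521 rows exactly 1 gene symbol, 1814 rows several and 16010 none, and rows of the last 2 kinds were left out of the gene-level tests. 23328 of the 23521 rows were matched by Entrez ID to a RefSeq gene table (GRCm38.p6), and 0 symbols needed updating. Where a gene had several rows, the row with the highest mean over the 6 arrays stood for it, which left 22180 genes, 1082 of them with more than 1 row. No filter on low values was applied.

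Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 28 lists with at least 5 measured genes, with camera at an estimated correlation, rank-based camera and fry as alternatives. fry asks whether a list's genes move one way on balance and does not compare the list with other genes. The design, 30 gene lists, the main settings and most alternatives were fixed before the data were examined. The genes named are Mpp5, Six2, Six3, the sex-linked genes, the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap (predicted, Rik, microRNA, small nucleolar RNA and olfactory or vomeronasal receptor loci not named), and in each list the 4 members of smallest p and up to 8 members past the threshold. Itgb6, Kirrel, Cd2ap, Cldn16, Cldn8, Cldn12, Hsph1, Synpo, Umod, Slc12a1, Aqp1, Mki67, Slco1a1 and the genes of NAD, vitamin D and phosphate metabolism and of adrenal and muscle tissue in the closing section were named after their values were seen. List members without a row of their own, such as C3 and Spp1, were not analysed here.

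The gene and list tests were checked on simulated data with the real genes' means and spreads. In a simulated comparison of 22180 genes, limma called 32% of 100 genes changed by 0.5, 94% of 50 genes changed by 1 and 100% of 50 genes changed by 2 on the log2 scale, and 6 unchanged genes. A simulated list of 25 genes shifted by 0.5 was called by camera and an unshifted one was not. The simulated genes were drawn independently, while correlations estimated in the real lists ran from -0.004 to 0.82. The check therefore does not cover false list calls that correlation causes at the preset value. Far fewer genes were changed there than the 21.8% called in the data, so the recovered shares may not carry over.

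Alternatives were a second quantile normalization, median centring, leaving out genes below the median level, eBayes with trend and robust settings, array weights, the mean of all rows of a gene, every row of the table, other thresholds, the replicate number as a block and leaving out each array in turn. After the data were examined, a sex term read from Xist and the Y-linked genes, this term together with an estimated correlation, male arrays alone (where the single Cre-negative array is assumed to vary like the others), leaving out genes on the X and Y chromosomes, and leaving out both arrays with transcripts of other tissues were added. Gene tables were joined and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.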

Results

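Gene expression was measured in 6 kidney samples of mice aged 4 weeks, each on 1 single-colour Affymetrix whole-transcript array. The series addresses what a reduced dose of Pals1 in nephrons does to the kidney. Pals1, encoded by Mpp5, is a scaffold protein of the apical Crumbs polarity complex. The labels name a conditional Mpp5 line and Six2-Cre transgenic mice, in which Cre recombinase is made in the progenitors of nephron epithelia and not in those of the collecting duct, on a mixed background. 3 samples were labelled Cre-negative and 3 Cre-positive. The number of conditional Mpp5 alleles behind each sample is not stated in the sources used here. The deposited table held 41345 probe sets as log2 values after RMA, of which 22180 genes with 1 probe set each were tested. Array medians over all probe sets lay between 5.55 and 5.64. Pearson correlations over the tested genes were 0.9898 to 0.9947 between arrays of the same group and 0.9727 to 0.9752 between groups. The first principal component, with 68.2% of the variance, separated the groups. Differences below are log2 fold changes, Cre-positive minus Cre-negative, ± SE from the limma fit with n = 3 per group, unless stated otherwise. The number of arrays limits their precision, and as the labels do not say whether each sample came from a separate mouse, p-values measure only the spread between these 6 samples, which may be technical in part.

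Mpp5 transcript (probe set 17276714, Entrez gene 56217) was lower in the samples labelled Cre-positive. Its level was 8.71 ± 0.06 (SD, n = 3) in Cre-negative and 8.10 ± 0.09 (SD, n = 3) in Cre-positive arrays, a difference of -0.61 ± 0.09 with limma adjusted p = 0.00232. On the linear scale the Cre-positive level was 0.654 of the Cre-negative level (95% interval 0.569 to 0.753), or 34.6% lower. All 3 Cre-positive values lay below all 3 Cre-negative values, and the exact two-sided permutation test gave p = 0.10, the smallest p that 3 against 3 arrays allow. The samples also hold cells outside the nephron lineage, so the 34.6% does not measure the share of Mpp5 that was deleted. Transcripts of several nephron segments fell in the same arrays (below), and cell makeup was not separated from a loss of Mpp5. Whether the probe set covers the exons that Cre removes is not stated in the sources used here. The Mpp5 difference is therefore only a limited check of the labels. With male arrays alone the difference was -0.68 with limma adjusted p = 0.0622 (0.00097 to 0.0622 over all alternatives). Six2, whose regulatory sequence drives the Cre transgene (-0.04 ± 0.12), and its neighbour Six3 (0.03 ± 0.12) did not pass the test, with limma adjusted p = 0.850 and 0.917. Among the 22 measured genes of the apical-basal polarity complexes, 3 fell and 1 rose, against 3 and 3 when adjusted over the list alone. These 4 of 22 are not above the 21.8% called over all tested genes, and 1 of them is Mpp5 itself. Besides Mpp5, the members that fell were Lin7a (-0.90 ± 0.13), a binding partner of Pals1, and Prkcz (-0.70 ± 0.11), an atypical protein kinase C, and the member that rose was Llgl1 (0.42 ± 0.08), a basolateral polarity protein. The list as a whole did not pass, with a median of -0.0029, and -0.02 against the male Cre-negative array (limma camera adjusted p = 0.813, adjusted p = 0.857 with an estimated correlation). 3 of its 4 calls held with the sex term, not that of Llgl1.

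**Figure D1:**
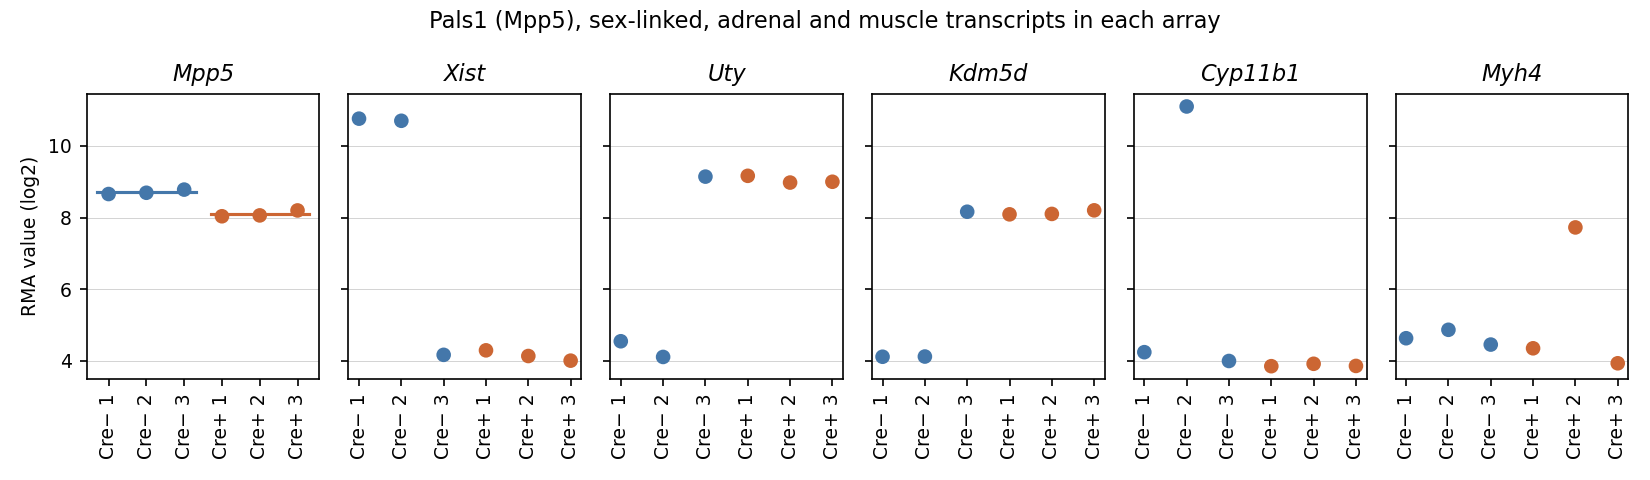
RMA value (log2, y axis) of 6 genes in each of the 6 arrays (x axis, Cre-negative in blue, Cre-positive in orange, horizontal bars the Mpp5 group means). Mpp5 is lower in every Cre-positive array, Xist is at 10.76 and 10.70 in Cre-negative replicates 1 and 2 only, and Cyp11b1 and Myh4 each stand out in 1 array.

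The arrays were not balanced for sex, which the labels used here do not give. Xist, the RNA that silences an X chromosome in females, stood at 10.76 and 10.70 in Cre-negative replicates 1 and 2 and at 4.16 in Cre-negative replicate 3, with 4.14 ± 0.14 (SD, n = 3) in the Cre-positive arrays. The Y-linked genes Uty, Kdm5d and Eif2s3y showed the opposite pattern: Uty was at 4.54 and 4.10 in Cre-negative replicates 1 and 2, at 9.14 in Cre-negative replicate 3 and at 9.05 ± 0.10 (SD, n = 3) in Cre-positive arrays. None of these 4 genes passed limma's test between groups over all genes (adjusted p = 0.0869 to 0.106), while adjusted over the list alone 3 were higher and 1 was lower in Cre-positive arrays, as at an unadjusted p under 0.05. Thus 2 of 3 Cre-negative arrays and 0 of 3 Cre-positive arrays carried female transcripts, so the median difference from the 1 male Cre-negative array is given below beside that of each tested list, with the number of its calls that held with sex as a second factor (the sex term). As sex varied only among Cre-negative arrays, the sex term's estimate for a gene is this same difference, with a larger SE for a given spread. The 2 are therefore not separate evidence. A call can be lost through that SE alone, so a lost call is no evidence of a sex effect. Cre-negative replicate 2 also carried transcripts of adrenal steroid synthesis, with Cyp11b1 at 11.10 against 3.85 to 4.24 in the other 5 arrays, and Cre-positive replicate 2 carried skeletal muscle transcripts, with Myh4 at 7.72 against 3.93 to 4.86.

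At limma adjusted p under 0.05, 4844 of the 22180 genes differed, 2372 higher and 2472 lower in Cre-positive kidneys, and 478 and 464 of these differed by at least 2-fold. The groups did not overlap for 4840 of the 4844 genes. Of all tested genes, 38.5% had groups that did not overlap, where chance gives 10%. Predicted, Rik, small RNA and olfactory receptor loci aside, the largest rise over all arrays was that of Havcr1, which encodes kidney injury molecule 1, at 29.4-fold (4.88 ± 0.42, adjusted p = 0.000269). It was followed by Serpina3n, an acute-phase protease inhibitor (4.46 ± 0.36), Fgg, the fibrinogen gamma chain (3.79 ± 0.19), and Lcn2, which encodes the injury marker neutrophil gelatinase-associated lipocalin (3.70 ± 0.12). The other 8 of the 12 largest rises were Lgi2 (3.56 ± 0.34), Ms4a4a (3.50 ± 0.18), the keratin gene Krt20 (3.39 ± 0.23), Cyp27b1, the 1-alpha-hydroxylase that activates vitamin D (3.34 ± 0.15), Serpina10 (3.21 ± 0.17), the monocyte chemoattractant Ccl2 (3.16 ± 0.20), the matrix protein gene Ltbp2 (3.13 ± 0.23) and the metalloproteinase inhibitor Timp1 (3.12 ± 0.42). The largest fall over all arrays was that of Slc22a19, an organic anion transporter, at 37.4-fold (-5.22 ± 0.24, adjusted p = 3.45e-05). The nuclease gene Dnase1 (-5.05 ± 0.16), the transporters Slc22a22 (-4.55 ± 0.33) and Slc22a7 (-3.78 ± 0.23), the brush border protease gene Mep1b (-4.18 ± 0.14) and the phosphate transporter Slc34a3 (-3.48 ± 0.15) also fell. The remaining 6 of the 12 largest falls were Akr1c18 (-4.97 ± 0.55), Akr1c14 (-3.47 ± 0.58), Serpina1d (-4.22 ± 0.42), Cyp2d12 (-3.70 ± 0.35), Rdh16f2 (-3.65 ± 0.50) and Clec2h (-3.53 ± 0.46). These 6 genes, like Slc22a19 and Serpina3n above, belong to families of closely similar genes, so the assignment of their probe sets to 1 member is uncertain. Some levels were near those of absent transcripts, as Y-linked genes stood at 3.66 to 4.54 in Cre-negative replicates 1 and 2. Akr1c18, Slc22a7 and Akr1c14 had means of 4.61 to 4.69 in Cre-positive arrays, and Ms4a4a of 4.06 in Cre-negative arrays. Their changes may be understated, so the order of the largest rises and falls is not secure. Against the male Cre-negative array alone, all 24 genes kept their direction, but not their order. The kept direction is no test of sex, as these genes were chosen for groups that did not overlap. The rises ran from 2.85 to 4.16 for Fgg, with Havcr1 at 4.03, and the falls from -2.47 for Rdh16f2 to -5.31 for Slc22a22, with Slc22a19 at -5.01, Akr1c18 at -4.03, Akr1c14 at -5.01 and Serpina1d at -3.44. With sex as a second factor 2030 genes were called, of which 1922 were among the 4844 in the same direction; the count was 1853 without Cre-negative replicate 2 and Cre-positive replicate 2, 1101 with male arrays alone (3 against 1) and 3141 without Cre-negative replicate 1.

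**Figure D2:**
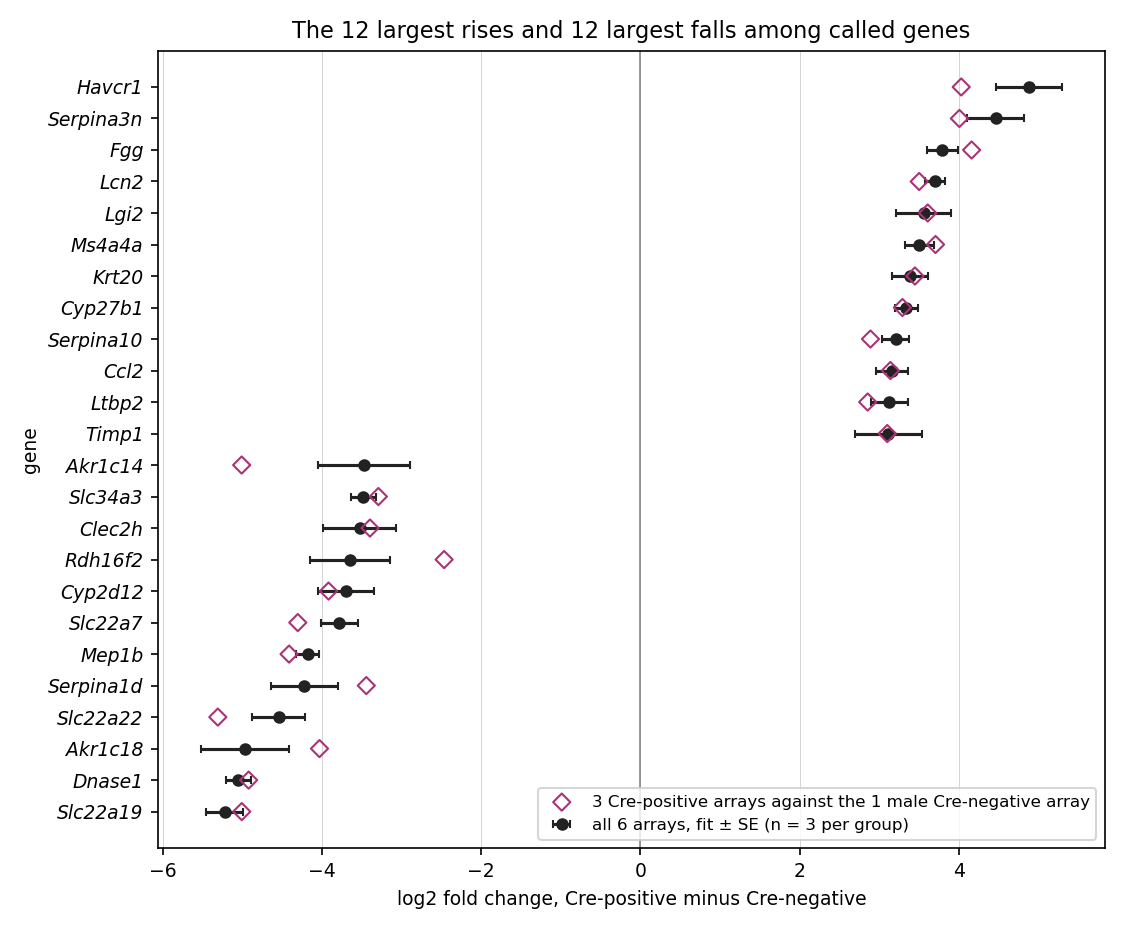
Log2 fold change, Cre-positive minus Cre-negative (x axis), of the 12 largest rises and 12 largest falls among the named called genes (y axis), as the limma estimate ± SE over all 6 arrays (filled circles, n = 3 per group) and as the difference of the 3 Cre-positive arrays from the 1 male Cre-negative array (open diamonds). Each gene lies on the same side of 0 in both, as the choice of genes whose groups did not overlap requires. Over all arrays the values run from -5.22 for Slc22a19 to 4.88 for Havcr1.

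Of 28 gene lists of at least 5 measured genes, 11 were higher and 8 lower in Cre-positive kidneys by limma's camera test with its preset correlation of 0.01, and 2 of the 19 held with a correlation estimated from these arrays. With the sex term as well, limma's camera called 0 lists at an estimated correlation, with 5 at an unadjusted p under 0.05, and 20 at the preset. Other splits of the 6 arrays also gave up to 15 list calls with the preset correlation. Each of those splits keeps a part of the Cre difference, so these calls do not measure chance. As few list calls held with an estimated correlation, each list is described by its members, with both p-values. Genes of tubular injury and dedifferentiation rose together. Of 29 measured members 26 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. The median was 1.57, and 1.70 against the male Cre-negative array (limma camera adjusted p = 3.15e-22, adjusted p = 0.0359 with an estimated correlation). 26 of its 27 calls held with the sex term, not that of Itgb6. Besides Havcr1, Lcn2, Fgg, Krt20 and Timp1, the rises included Sox9, a transcription factor of regenerating tubules (2.07 ± 0.11), the keratin gene Krt18 (1.72 ± 0.11), the cell cycle inhibitor Cdkn1a (1.57 ± 0.10), S100a6 (2.10 ± 0.14), Anxa3 (1.77 ± 0.09) and Lgals3, which encodes galectin-3 (1.49 ± 0.08). The member that fell was the integrin gene Itgb6 (-0.94 ± 0.18). Immediate early and heat shock genes, which respond to stress and to handling of tissue, rose in the same arrays. 10 of 15 rose and 1, Hsph1, fell (11 and 1 adjusted over the list alone), and the rises included Ier3 (1.19 ± 0.13), Egr1 (1.19 ± 0.19), Fos (1.03 ± 0.19) and Atf3 (1.01 ± 0.14). The median was 0.77, and 0.81 against the male Cre-negative array (limma camera adjusted p = 2.36e-05, adjusted p = 0.0823 with an estimated correlation). 5 of its 11 calls held with the sex term, not that of Hsph1.

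**Figure D3:**
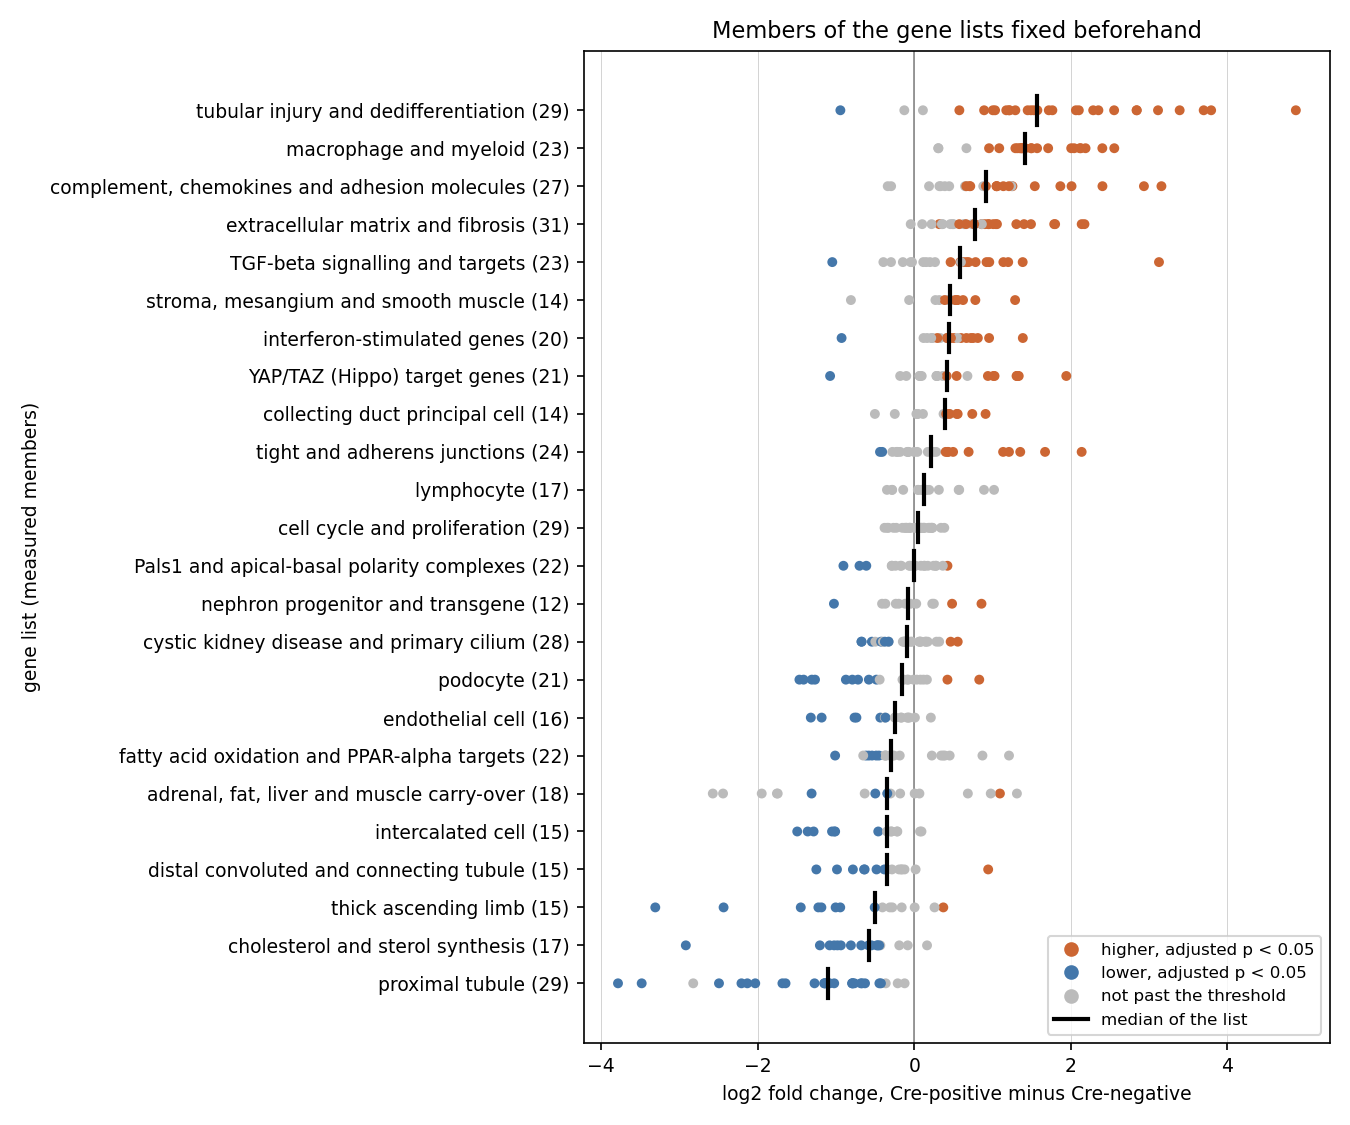
Log2 fold change, Cre-positive minus Cre-negative (x axis), of each measured member (points) of the pathway and cell type lists with at least 5 measured genes (y axis, number of members in brackets), coloured by whether limma's adjusted p was under 0.05, with the median of each list as a black bar. Medians run from -1.10 for proximal tubule genes to 1.57 for tubular injury genes.

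Transcripts of the proximal tubule fell. Of 29 measured genes 25 fell and 0 rose (26 and 0 adjusted over the list alone). The median was -1.10, and -1.06 against the male Cre-negative array (limma camera adjusted p = 5.66e-16, adjusted p = 0.0359 with an estimated correlation). 18 of its 25 calls held with the sex term. The falls included the endocytic receptor genes Lrp2 (-1.11 ± 0.10) and Cubn (-1.14 ± 0.12), which encode megalin and cubilin, the glucose transporter Slc5a2 (-2.49 ± 0.16), the organic anion transporter Slc22a8 (-2.13 ± 0.20) and the enzymes Gatm (-2.03 ± 0.19) and Miox (-1.64 ± 0.19). The water channel gene Aqp1 did not pass (-0.21 ± 0.12). In the thick ascending limb list 8 of 15 genes fell and 1 rose (10 and 1 adjusted over the list alone). Egf, the precursor of epidermal growth factor, fell by 9.90-fold (-3.31 ± 0.27), Wfdc15b by 5.41-fold (-2.44 ± 0.16) and Cldn10 by 2.01-fold, Cldn16 rose (0.37 ± 0.11), and Umod (-0.28 ± 0.09) and Slc12a1 (-0.41 ± 0.13) did not pass. The median was -0.50, and -0.60 against the male Cre-negative array (limma camera adjusted p = 2.36e-05, adjusted p = 0.287 with an estimated correlation). Without genes below the median level the list median was -0.94. 7 of its 9 calls held with the sex term, not that of Cldn16. In the distal convoluted and connecting tubule list 8 of 15 fell, among them the sodium chloride cotransporter Slc12a3 (-0.78 ± 0.12) and the magnesium channel Trpm6 (-0.63 ± 0.10), and 1 rose, the calcium channel Trpv5 (0.95 ± 0.13). The counts were unchanged when adjusted over the list alone. The median was -0.35, and -0.21 against the male Cre-negative array (limma camera adjusted p = 0.000830, adjusted p = 0.4005 with an estimated correlation). 1 of its 9 calls held with the sex term, not those of Slc12a3 and Trpm6.

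Podocyte genes moved in both directions. Of 21 measured genes 9 fell, 2 rose and 10 did not pass (10 and 2 past the threshold adjusted over the list alone). Nphs1, which encodes the slit diaphragm protein nephrin (-1.41 ± 0.14), Podxl, podocalyxin (-1.27 ± 0.15), Ptpro (-1.47 ± 0.19), Clic3 (-1.31 ± 0.14), Col4a3 (-0.79 ± 0.10) and the transcription factor gene Wt1 (-0.87 ± 0.15) fell. Kirrel (0.83 ± 0.18) and Cd2ap (0.42 ± 0.09), which also encode slit diaphragm components, rose, and Synpo did not pass (-0.01 ± 0.12). The list median was -0.15, and -0.17 against the male Cre-negative array (limma camera adjusted p = 0.00380, adjusted p = 0.354 with an estimated correlation). The median was -0.25 without Cre-negative replicate 3, -0.24 without Cre-positive replicate 3 and -0.29 without genes below the median level. 7 of its 11 calls held with the sex term, not those of Wt1 and Cd2ap. In the collecting duct, 6 of 14 principal cell genes rose and 0 fell (7 and 1 adjusted over the list alone), including the water channel Aqp2 (0.91 ± 0.23) and the sodium channel subunits Scnn1b (0.54 ± 0.12) and Scnn1g (0.56 ± 0.12). The median was 0.39, and 0.42 against the male Cre-negative array (limma camera adjusted p = 0.0117, adjusted p = 0.447 with an estimated correlation), and limma's fry gave adjusted p = 0.106 (0.00214 to 0.447 over all alternatives). Without Cre-positive replicate 1 the list median was 0.24. 3 of its 6 calls held with the sex term, not that of Aqp2. Of 15 intercalated cell genes 7 fell and 0 rose (8 and 0 adjusted over the list alone), including the anion exchangers Slc26a4 (-1.36 ± 0.21), Slc26a7 (-1.29 ± 0.12) and Slc4a1 (-1.02 ± 0.15). The median was -0.35, and -0.21 against the male Cre-negative array (limma camera adjusted p = 2.46e-05, adjusted p = 0.354 with an estimated correlation). 4 of its 7 calls held with the sex term, not those of Slc26a4 and Slc4a1.

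Macrophage and myeloid transcripts rose, and lymphocyte transcripts did not pass the test. Of 23 myeloid genes 20 rose and 0 fell (21 and 0 adjusted over the list alone), including Cd14 (2.56 ± 0.12), Itgam (2.40 ± 0.23), Cd68 (2.13 ± 0.21), the lysozyme gene Lyz2 (2.12 ± 0.23) and the mannose receptor gene Mrc1 (2.01 ± 0.27). The median was 1.42, and 1.51 against the male Cre-negative array (limma camera adjusted p = 6.76e-13, adjusted p = 0.354 with an estimated correlation). 9 of its 20 calls held with the sex term. None of 17 lymphocyte genes passed limma's test, over all genes or adjusted over the list alone, and 3 were higher and 3 lower at an unadjusted p under 0.05. Cd52 was at 1.02 ± 0.34 and Cd3e at 0.57 ± 0.24, and the list median was 0.13, and 0.23 against the male Cre-negative array (limma camera adjusted p = 0.412, adjusted p = 0.814 with an estimated correlation). Cd52 and Cd3e stood at 6.24 and 6.26 in Cre-positive replicate 1, the lowest of the Cre-positive arrays. Without that array limma's camera called the lymphocyte list higher, with a median of 0.29 and adjusted p = 0.00522 (0.00522 to 0.897 over all alternatives). In the list of complement, chemokine and adhesion genes 16 of 27 rose and 0 fell (20 and 0 adjusted over the list alone). The median was 0.92, and 0.90 against the male Cre-negative array (limma camera adjusted p = 5.49e-12, adjusted p = 0.258 with an estimated correlation). 10 of its 16 calls held with the sex term. The rises included Ccl2, the adhesion molecules Vcam1 (2.94 ± 0.21) and Icam1 (1.21 ± 0.10), Cxcl1 (1.87 ± 0.12), the macrophage growth factors Il34 (2.41 ± 0.15) and Csf1 (1.54 ± 0.17) and the complement gene C4b (2.01 ± 0.16). Of 20 interferon-stimulated genes 12 rose, such as Oas2 (1.39 ± 0.18) and Irf7 (0.96 ± 0.15), and 1, Rsad2, fell (-0.93 ± 0.20), with 14 and 1 adjusted over the list alone. The median was 0.45, and 0.47 against the male Cre-negative array (limma camera adjusted p = 4.50e-06, adjusted p = 0.354 with an estimated correlation). 3 of its 13 calls held with the sex term, not that of Rsad2. Of 16 endothelial genes 6 fell and 0 rose, with the same counts adjusted over the list alone, including the VEGF receptor gene Kdr (-1.18 ± 0.13) and Ehd3, a glomerular endothelial gene (-1.32 ± 0.17). The median was -0.25, and -0.21 against the male Cre-negative array (limma camera adjusted p = 0.00320, adjusted p = 0.422 with an estimated correlation). It was -0.16 without Cre-positive replicate 1, -0.14 without Cre-positive replicate 2 and -0.15 without both arrays with transcripts of other tissues. 2 of its 6 calls held with the sex term.

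Matrix genes rose. Of 31 members 19 rose and 0 fell (24 and 0 adjusted over the list alone), including the matrix protease Mmp14 (1.80 ± 0.11), the collagen cross-linking enzyme Lox (2.14 ± 0.18), Col12a1 (2.18 ± 0.25), Col1a1 (1.49 ± 0.22), tenascin C, Tnc (1.79 ± 0.21), and fibronectin, Fn1 (1.40 ± 0.19). The median was 0.77, and 0.79 against the male Cre-negative array (limma camera adjusted p = 1.89e-12, adjusted p = 0.354 with an estimated correlation). 9 of its 19 calls held with the sex term. In the TGF-beta list 12 of 23 rose and 1 fell (13 and 2 adjusted over the list alone). Tgfb1 (1.14 ± 0.15), its receptors Tgfbr1 (0.78 ± 0.10) and Tgfbr2 (0.69 ± 0.10) and the target Tgfbi (1.39 ± 0.18) rose, while Bmp7, a morphogen of the same family, fell (-1.05 ± 0.09). The median was 0.59, and 0.52 against the male Cre-negative array (limma camera adjusted p = 7.57e-05, adjusted p = 0.354 with an estimated correlation). 7 of its 13 calls held with the sex term, not that of Tgfbr2. Of 21 YAP/TAZ target genes, the transcriptional output of the Hippo pathway, 10 rose and 1 fell (13 and 1 adjusted over the list alone). Ankrd1 (1.94 ± 0.24), Ccn2 (1.34 ± 0.12), Ccn1 (1.31 ± 0.19), Myof (1.32 ± 0.12) and Axl (1.03 ± 0.16) rose, while Igfbp3 fell (-1.07 ± 0.14). The median was 0.41, and 0.52 against the male Cre-negative array (limma camera adjusted p = 4.50e-06, adjusted p = 0.258 with an estimated correlation). 9 of its 11 calls held with the sex term. Of 14 stromal, mesangial and smooth muscle genes 7 rose and 0 fell (8 and 1 adjusted over the list alone), such as Tagln (1.29 ± 0.23), Acta2 (0.78 ± 0.17) and Pdgfra (0.56 ± 0.13). The median was 0.46, and 0.46 against the male Cre-negative array (limma camera adjusted p = 0.000381, adjusted p = 0.287 with an estimated correlation). 1 of its 7 calls held with the sex term, not those of Tagln, Acta2 and Pdgfra. Among 24 junction genes 10 rose and 2 fell (12 and 3 adjusted over the list alone). The rises were led by Cldn4 (2.14 ± 0.10), Cdh3 (1.67 ± 0.12), Cldn3 (1.35 ± 0.15) and Cldn7 (1.21 ± 0.13), while Cldn8 (-0.41 ± 0.11) and Cldn12 (-0.44 ± 0.12) fell. The median was 0.21, and 0.29 against the male Cre-negative array (limma camera adjusted p = 0.00857, adjusted p = 0.391 with an estimated correlation), and rank-based camera gave adjusted p = 0.0546 (0.000586 to 0.391 over all alternatives). 6 of its 12 calls held with the sex term, not those of Cldn8 and Cldn12.

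Transcripts of cholesterol synthesis fell. Of 17 measured genes 13 fell and 0 rose (14 and 0 adjusted over the list alone), including Cyp51, lanosterol demethylase, at 7.56-fold lower (-2.92 ± 0.22), Nsdhl (-1.20 ± 0.16), Mvd (-1.08 ± 0.10), Hmgcs1 (-1.02 ± 0.13) and the sterol sensor gene Insig1 (-0.81 ± 0.13). The median was -0.58, and -0.68 against the male Cre-negative array (limma camera adjusted p = 6.25e-08, adjusted p = 0.258 with an estimated correlation). 7 of its 13 calls held with the sex term, not that of Insig1. In the fatty acid oxidation list 6 of 22 fell and 0 rose (7 and 0 adjusted over the list alone), among them Acadm, medium-chain acyl-CoA dehydrogenase (-1.01 ± 0.11), Ppara (-0.54 ± 0.12) and Ppargc1a (-0.45 ± 0.09), in arrays where 25 of 29 proximal tubule genes fell (median -1.10). The median was -0.30, and -0.36 against the male Cre-negative array (limma camera adjusted p = 0.0376, adjusted p = 0.681 with an estimated correlation). It was -0.47 without Cre-positive replicate 1 and -0.20 without Cre-positive replicate 3. 1 of its 6 calls held with the sex term, not those of Ppara and Ppargc1a. That list was not called in 10 of 21 alternatives, among them those without Cre-negative replicate 3, Cre-positive replicate 2 or Cre-positive replicate 3 (limma camera adjusted p = 0.0545, 0.144 and 0.261, against 0.000262 to 0.735 over all alternatives). None of 29 cell cycle genes passed limma's test, over all genes or adjusted over the list alone, and 1 was higher and 1 lower at an unadjusted p under 0.05. The proliferation marker Mki67 was at -0.0004 ± 0.32 and Tyms at -0.35 ± 0.11. The list median was 0.05, and -0.16 against the male Cre-negative array (limma camera adjusted p = 0.621, adjusted p = 0.900 with an estimated correlation), and -0.02 and -0.01 after a second quantile normalization and median centring. Without Cre-positive replicate 1 limma's camera called the list higher, with a median of 0.22 and adjusted p = 0.00385 (0.00385 to 0.90 over all alternatives). Of 28 cystic disease and cilium genes 6 fell and 2 rose (7 and 2 adjusted over the list alone). Ift122 (-0.67 ± 0.11), Bbs1 (-0.67 ± 0.12) and Cep290 (-0.54 ± 0.10) fell, while Pkd1, which encodes polycystin-1 (0.56 ± 0.09), and Bicc1 (0.47 ± 0.12) rose. The median was -0.09, and -0.01 against the male Cre-negative array (limma camera adjusted p = 0.277, adjusted p = 0.402 with an estimated correlation). 1 of its 8 calls held with the sex term, not those of Bbs1, Cep290, Pkd1 and Bicc1. limma's fry, which asks only whether the list moves one way on balance, gave adjusted p = 0.0158, the lowest over all alternatives (0.0158 to 0.586).

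Of 12 nephron progenitor genes 2 rose, Pax8 (0.86 ± 0.10) and Pax2 (0.48 ± 0.10), and 1, Lhx1, fell (-1.03 ± 0.08), with the same counts adjusted over the list alone. The median was -0.08, and -0.15 against the male Cre-negative array (limma camera adjusted p = 0.880, adjusted p = 0.900 with an estimated correlation). 3 of its 3 calls held with the sex term, and 3 of 12 is near the 21.8% called over all tested genes. Of 15 circadian clock genes 6 rose, such as Per1 (1.23 ± 0.21), Cry1 (0.85 ± 0.16) and Cry2 (0.90 ± 0.17), and 2 fell, Hlf (-0.59 ± 0.08) and Arntl (-0.57 ± 0.16), with 7 and 2 adjusted over the list alone. The median was 0.34, and 0.14 against the male Cre-negative array (limma camera adjusted p = 0.156, adjusted p = 0.422 with an estimated correlation). Without genes below the median level it was 0.04. 2 of its 8 calls held with the sex term, not those of Per1, Cry2 and Arntl. As limma's camera tests a shift one way, its result does not show that a list whose members move both ways is unchanged. Of 14 neighbours of Mpp5 3 rose and 2 fell (3 and 3 adjusted over the list alone), with Arg2, which encodes arginase 2 (1.94 ± 0.22), and Zfp36l1 (0.80 ± 0.10) among the rises and Gphn (-0.65 ± 0.08) among the falls. Their median was 0.02, 0.14 against the male Cre-negative array and -0.04 after either rescaling (limma camera adjusted p = 0.511, adjusted p = 0.659 with an estimated correlation). 4 of its 5 calls held with the sex term. In the list of adrenal, fat, liver and muscle genes 3 of 18 fell and 1 rose, with the same counts adjusted over the list alone, with the albumin gene Alb (-1.31 ± 0.34) among the falls and the transthyretin gene Ttr (1.10 ± 0.22) the rise. The median was -0.34, and -0.10 against the male Cre-negative array (limma camera adjusted p = 0.277, adjusted p = 0.604 with an estimated correlation). It was -0.12 without Cre-negative replicate 2, the array with adrenal transcripts, and -0.20 without Cre-positive replicate 2 as well. 0 of its 4 calls held with the sex term, and 4 of 18 is near the 21.8% called over all tested genes. Of 9 genes known to differ between male and female kidneys 2 fell, Akr1c18 and Slc22a28 (-3.12 ± 0.56, and -4.55 against the male Cre-negative array), and 0 rose, with the same counts adjusted over the list alone. The median was 0.03, -1.52 against the male Cre-negative array and negative after either rescaling, while the mean was -1.05 and the direction of limma's camera test was lower, without passing (limma camera adjusted p = 0.248, adjusted p = 0.684 with an estimated correlation). 2 of its 2 calls held with the sex term. Without Cre-negative replicate 1 it was called lower at the preset correlation (adjusted p = 0.0438, 4.24e-10 to 0.711 over all alternatives). The erythroid list, with 4 measured genes, was too short to test, and in it 1 gene fell, Slc4a1, shared with intercalated cells, with the same count adjusted over the list alone.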

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

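Probe sets outside the gene-level comparison also differed between the groups. Of 17824 rows without exactly 1 gene symbol, 1313 passed the threshold in a limma fit to every row, 881 higher and 432 lower in Cre-positive than in Cre-negative arrays. This is a smaller share than the 21.8% called among the tested genes. The split was not repeated after median centring, which moved the calls of the tested genes from 49.0% to 37.3% higher. The rows were singled out because they are a signal in data that the comparisons of the report do not use, and they cannot be assigned to genes here.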

How the results depend on the processing

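The alternatives that use sex or the arrays with transcripts of other tissues were chosen after seeing the data. The count of 4844 genes moved to 2030 with a sex term, 1101 with male arrays alone, 1853 without Cre-negative replicate 2 and Cre-positive replicate 2, 2496 with an added limit of 1.5-fold and 2663 at an unadjusted p under 0.05 with that limit. The sex term and the smaller sets of arrays leave fewer degrees of freedom. Leaving out each array in turn gave 3141 to 4885 genes, the lowest without Cre-negative replicate 1. All other settings gave 3977 to 6396 genes, with 3977 for the replicate block, which changed no list call and left Mpp5 at -0.61, past the threshold. Same-numbered arrays share only a number: their deviations from the group means correlated at 0.03, -0.04 and -0.01, and not every array correlated best with its own number. Of the calls, 49.0% were higher in Cre-positive arrays in the values reported above (2372 against 2472) and 37.3% after median centring (1861 against 3134), which moved the median of all genes from -0.01 to -0.07. The Mpp5 difference was negative under every setting, past the threshold in all but 1, and ran from -0.66 to -0.58 when 1 array was left out. With male arrays alone it was -0.68 with limma adjusted p = 0.0622 (0.00097 to 0.0622 over all alternatives). The 19 list calls became 2 with an estimated correlation and 0 with this and the sex term together (5 at an unadjusted p under 0.05), stayed at 18 to 21 when 1 array was left out and at 18 to 20 under the remaining settings. No list that was called reversed under any setting. Cyp2j13, not called at 2.12 ± 1.31 over all arrays, reversed to -1.52 with the sex term and to -1.52 with male arrays alone. The sex term ended the call of 71 of the genes named, and male arrays alone that of 107. For the other changes the cause was not tested. Linear-scale alternatives did not apply to log2 values and were not run, and signal over background cannot be read from this table.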

Other observations

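The tests of sex, of carried-over tissue, of dilution and of uniform loss, and the lists of NAD synthesis and of vitamin D and phosphate handling, were chosen after the results were seen.

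Several genes of the route from tryptophan to NAD and of NAD salvage were lower in Cre-positive kidneys. Of 14 measured genes 9 fell and 0 rose. Acmsd (-3.14 ± 0.30), which diverts an intermediate away from NAD, and Haao (-2.52 ± 0.28), which acts upstream of that branch, fell most, with Ido2 at -1.71 ± 0.15. Qprt (-0.11 ± 0.14), which carries the route on from quinolinate towards NAD, and Nampt, of the salvage route (-0.09 ± 0.13), did not pass. The list median was -0.78, and -0.75 against the male Cre-negative array, and 6 of the 9 calls held with the sex term. None of its genes is in the proximal tubule list (median -1.10), though several of these enzymes are known from that segment. Genes of vitamin D and phosphate handling changed in both directions, 4 up and 6 down of 14, and 6 of these calls held with the sex term, not that of Vdr. Of its genes 2, Slc34a1 and Slc34a3, are also in the proximal tubule list. Cyp27b1 rose by 10.1-fold and the phosphate transporter Slc34a2 rose (2.23 ± 0.19). The transporters Slc34a1 (-0.76 ± 0.09) and Slc34a3 (-3.48 ± 0.15), the FGF23 co-receptor gene Kl (-1.32 ± 0.13), the parathyroid hormone receptor gene Pth1r (-1.18 ± 0.10) and Vdr (-0.54 ± 0.12) fell. Both lists were written after their genes' values were seen, so a list test would be no independent evidence and none is given.

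The large number of genes that differ between the groups could come from the uneven sex of the mice or from tissue carried over in single arrays. Genes were called from 2 against 2 arrays that included Cre-negative replicate 2 and Cre-positive replicate 2, in each of the 4 possible ways (2731 to 3671 genes), and the difference between the 2 arrays left out was a median 0.834 to 0.876 of that in the calling arrays (lowest lower quartile 0.516), which argues against carried-over tissue as the whole cause. Genes called with both female Cre-negative arrays and 2 Cre-positive arrays gave, between the male Cre-negative array and the Cre-positive array left out, a median of 0.834 to 0.972, but this rests on 1 male Cre-negative array, so sex stays open. Only 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, called as many genes (4844, highest other 0 by limma, or 724 at an unadjusted p under 0.05 against 7418). Likewise 1 of 10 called as many lists (19, highest other 15), but 10 splits are too few for a share under 0.05. Every other split also mixes the Cre groups. Part of the Cre difference then stays between its groups and the rest adds to the spread within them, so its counts do not measure chance. The mixed genetic background stays open and untested.

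Single arrays held transcripts of other tissues. In Cre-negative replicate 2, Star, Cyp11b1, Cyp21a1, Cyp11a1 and Hsd3b1 exceeded the mean of the other arrays by 4.94 to 7.13 on the log2 scale, and of 21 further adrenal cortex and medulla genes, listed before their values were read, 16 were highest there, with Chgb at 3.48, Chga at 3.03 and Th at 2.22 above the others. Of the 21, 8 lay above the median level of all genes in the other arrays too, and the pattern is consistent with adrenal tissue carried over with that kidney. Female sex was argued against by Cre-negative replicate 1, whose 5 steroidogenic genes lay a median 0.13 above the male arrays. In Cre-positive replicate 2, Acta1, Myh4 and Ckm exceeded the others by 2.11 to 3.28, and 13 of 18 further skeletal muscle genes, of which 3 lay above that median elsewhere, were highest there, led by Atp2a1 at 3.72, consistent with skeletal muscle carried over.

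The lower proximal tubule transcripts could come from dilution by other cells, from a uniform loss of proximal tubule cells or from sex. Cells that come in lower, by a like amount, all types that did not rise. The proximal tubule median minus the endothelial one was -0.85 (95% bootstrap interval -1.07 to -0.41). The interval left out 0 against 3 of 5 such types and not against the intercalated cell and thick ascending limb lists. The bootstrap drew list genes only, so it leaves out the spread between arrays. In Cre-negative arrays the median level was 11.7 for proximal tubule genes and 7.90 to 9.80 for the 5 other lists. RMA understates changes of dimmer genes, so the comparison cannot decide, and dilution stays open. A uniform loss lowers all the segment's genes alike, but for 16 of 29 genes the 95% interval left out the list median. The quartiles of the list were -1.68 and -0.68. These values argue against a uniform loss as the only cause. The intervals do not cover how far each probe set follows a change in RNA, so a uniform loss is not excluded. Against the male Cre-negative array the list median was -1.06 and all 29 genes were lower. The shared direction is no test of sex, as it is fixed for genes whose groups did not overlap. The median rests on 1 male Cre-negative array, so sex stays open. Lower transcription per cell, or a partial loss of cells together with it, also stays open, as a hypothesis that RNA of kidney tissue cannot test.

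Slco1a1 and Cyp2j13, known as male-biased kidney genes, were lower in the Cre-positive arrays than in the single male Cre-negative array. Slco1a1 stood at 8.56 in that array, at 3.96 and 3.96 in the female Cre-negative arrays and at 3.74 ± 0.27 (SD, n = 3) in the male Cre-positive arrays, and Cyp2j13 stood at 10.68, 5.35, 5.10 and 9.16 ± 0.37. With the sex term the list of sex-biased genes was called lower (median -1.52, limma camera adjusted p = 2.05e-09 at the preset correlation, against 4.24e-10 to 0.711 over all alternatives), but not with an estimated correlation (adjusted p = 0.0732), and the value rests on 1 male Cre-negative array. A brown fat list, chosen with the adrenal and muscle lists, had median excesses over the other arrays of 0.23, 0.22 and 0.41 in Cre-negative replicates 1 to 3 and of -0.12, -0.24 and -0.53 in Cre-positive replicates 1 to 3.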
